A study of Drosophila melanogaster with 2 samples.

How the data were processed

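Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a transgene for Arrowhead (Awh), a LIM-homeodomain transcription factor, fused to enhanced green fluorescent protein. Per the labels, the immunoprecipitation used an antibody against the fluorescent protein, although another label field names Awh itself as the antibody target. Chromatin was sheared by sonication to fragments of 200 to 800 bp. The series has 2 samples, biological replicates 1 and 2 of a single group, each from its own embryo collection as recorded by separate biosamples. No control library is among these samples. The labels name possible controls, which were not analysed here, so no group comparison exists and each list was described against positions or sequences of the genome.

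The deposited files are lists of peaks on the dm6 build, per the labels. Each replicate has a ranked list of all candidate peaks and a thresholded list. The series has the same pair made from both replicates together, in a stricter version named conservative and a broader version called optimal here. The aligner and the peak caller are not given in the sources used here. The deposited lists hold for each peak a signal value from the authors' peak caller, which was used only to describe and rank peaks within a list. They also hold a score, in the authors' files a whole number up to 1000 that lies within 1 unit of a rounded function of the irreproducible discovery rate (IDR), a measure of whether a peak keeps its rank between replicates. Every peak of the thresholded lists had a score of at least 830, which stands for an IDR of 0.01 or less. How the replicate lists were split to obtain an IDR is not given in the sources used here. Signal values were not rescaled between lists here, and the authors' scaling is not recorded, so ratios between the replicates' signals are descriptive. No list carries read totals, so the sequencing depth is unknown. Intervals on shares of regions (95%, Wilson) cover the number of regions only and treat regions as independent.

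Analyses used chromosomes 2L, 2R, 3L, 3R, 4 and X, on which 5024 of the 5026 conservative peaks lay. All peak ends fell within the lengths of these chromosomes in the reference used (Release 6, the assembly behind dm6), with Ensembl release 115 annotation (BDGP6.54). Overlapping peaks were merged into 1 region with the summit and signal of the strongest peak. The conservative list was the main set. For each region, the signal in each replicate was read from that replicate's own ranked list, as the strongest peak overlapping the region by at least 1 bp.

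Replicate overlap was the share of regions in the shorter replicate list that overlapped a region of the longer list by at least 1 bp. It was compared with 10000 circular shifts along each chromosome, 1-sided. Spearman's rho of the signals was computed across regions, which are not independent replicates, and carries no p-value. Its interval came from 1000 bootstrap samples of regions. Summits were assigned to promoters (within 500 bp of the start of a protein-coding transcript), 5' UTRs, coding exons, 3' UTRs, introns or intergenic sequence, in that order of precedence. Shares were compared with 10000 shifts, 2-sided. The smallest p these shifts can give is 0.0001 1-sided and 0.0002 2-sided. Signals of promoter and other regions were compared by a 2-sided permutation test of the difference of medians with 100000 resamples, whose smallest p is 1e-05.

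Sequence was read within 100 bp of each summit and in a window of the same width centred 1000 bp away, on a side drawn at random with a fixed seed. A site or hexamer was compared by an exact 2-sided sign test on regions where only 1 of the windows held it. The 19 fixed sites comprised TAATTA, a core site of LIM-homeodomain proteins, and sites of other embryonic factors. As controls they included 4 palindromes of the same base composition as TAATTA. All 2080 hexamers, counted on both strands together, were also tested. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05.

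A protein-coding gene was counted as bound when its transcript start was the nearest to at least 1 summit. Of 13945 protein-coding genes, 13741 have a stretch of chromosome whose nearest start is their own, called the territory here. The others share a start position with another gene. For 15 lists of genes, bound members were compared with all genes in the same of 20 bins of territory length, by an exact 2-sided conditional test. Of the listed symbols, cut, dys and Dl matched no single gene name in the annotation and were left out. The share of regions on X was compared with its share of length by an exact 2-sided binomial test. Named genes are Awh, the genes nearest to the 20 regions of highest signal that lay in both replicates' own lists, the 5 genes with the most regions, and in each list the 4 members with the strongest regions. The groups, tests, lists, sites, naming rule and alternative settings were set before the data were examined. The settings fixed in advance were the optimal list, each replicate's own list (leaving out the other), the stronger 50% of regions, unmerged peaks, other overlap rules, other promoter widths, other windows and GC-matched control windows (within 2 percentage points), and other rules of gene assignment. Alternatives chosen after seeing the data are named as such.

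The tests were run on simulated data. With hexamers written into random windows, the scan called 20 of 20 present in an added 8% of windows, 19 of 20 at 4% and 7 of 20 at 2%. With nothing added it called 0 of 2080. After the additions it also called 85 of the 2020 other hexamers, a set that includes those sharing bases with an added hexamer. Both sets of windows were random, so the simulation does not cover calls that come from a difference in base composition between summits and flanks. For lists of 30 genes, an unadjusted p below 0.05 came from 10 of 400 lists with no effect and 231 of 400 with 3 times the odds of binding, so lists of this size can miss such an effect. The promoter test called 2 of 40 random sets and 40 of 40 sets with 5% of summits moved to starts. Simulated summits were placed independently of each other, so this does not cover the clustering of real regions. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.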

Results

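The data are peak lists from ChIP-seq of Awh fused to a green fluorescent protein in whole embryos aged 0 to 24 h, with 2 biological replicates and no second group. Awh, or Arrowhead, is a LIM-homeodomain transcription factor known for its role in the abdominal histoblasts and the salivary gland imaginal ring, the precursors of adult tissue. The purpose of the experiment, per the labels, was to locate the protein on the genome. The questions addressed here are how many places were bound, whether both replicates named the same places, and which genes and sequences lay there. The read depth of the libraries is unknown from the lists.

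The strict list built from both replicates held 4781 bound regions, which covered 1.52 Mb of the 6 chromosomes analysed. The 2805 genes nearest to these regions made up part of the 13741 protein-coding genes that could be assigned, and 1881 of the 2805 had a single region while 140 had 5 or more. Replicate 1 alone gave 2895 regions and replicate 2 alone 3560. Of the 2895 regions of replicate 1, 2075 overlapped a region of replicate 2, a share of 71.7% (Wilson interval 70.0 to 73.3%). Shifted regions overlapped in 1.54% of cases on average and in at most 10.4%, with p = 0.0001 (1-sided permutation by shifts), the smallest these can give. Among the 4781 regions, 2072 (43.3%) lay in both replicates' own thresholded lists and had a median signal of 165. The 1282 regions (26.8%) found in neither replicate's own list had a median signal of 75.2. Across the 4741 regions with a candidate peak in both replicates, Spearman's rho of the 2 signals was 0.654 (bootstrap interval 0.636 to 0.672). The log2 ratio of replicate 1 to replicate 2 had a median of 0.02 and an SD of 0.49 across regions. The list was thresholded on agreement between replicates, which can narrow this spread, and in the optimal list the SD was 0.623. Single regions must be read against a spread of at least 0.49.

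**Figure D1:**
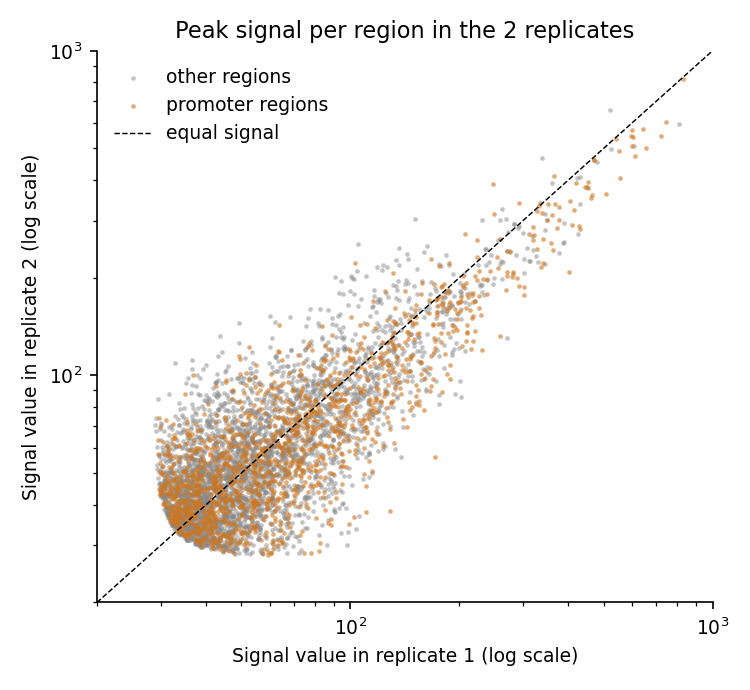
Each point is 1 of the 4741 regions with a peak in both replicates, with its signal value in replicate 1 on the x axis and in replicate 2 on the y axis, both on log scales. Points lie along the line of equal signal, with a Spearman's rho of 0.654, and promoter regions (orange) span the same range as other regions (grey).

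The strongest regions lay mostly at promoters. Ugalt, which encodes a transporter of UDP-galactose, had the highest signal of the list, 1644, at an X-linked promoter (X, 2703729 to 2704029, summit 43 bp upstream of the start). Its signals were 828 in replicate 1 and 817 in replicate 2. Of the 20 strongest regions, all present in both replicates' own lists, 15 were at promoters, 4 were intergenic and 1 was in an intron, that of CG11050 (2L, 6612557 to 6612865, signal 1420). Promoters in this group included CG14100 (signal 1342), ph-p, a Polycomb-group gene (1252), CG18549 (1202), CG7601 (1170), Tcs5 (1163), px (1106), PNPase, a mitochondrial exoribonuclease (1072), Fkbp14 (1040), Chro, a component of interband chromatin (966), RluA-1 (949) and CG5611 (936). The mitochondrial ribosomal protein genes mRpS10 (1134) and mRpL41 (1085) also had such regions, and the promoter region of CenG1A (1153) lay within 500 bp of the start of another such gene, mRpS23. The regions assigned to hll (1168), CG13323 (1132), tara (1023) and CG31668 (931) were intergenic, that of CG13323 with its summit 11909 bp from the start. Across the 20, the signal of replicate 1 was between 0.792 and 1.37 times that of replicate 2. The median signal of all 4781 regions was 105.

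The sequence of the 41 bp around the Ugalt summit (X, 2703875 to 2703915) was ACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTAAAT and holds no TAATTA. The strongest region with TAATTA within 20 bp of its summit was the promoter region of CG7601 (3R, 29736714 to 29736973, summit 98 bp upstream of the start, signals 600 and 571 in replicates 1 and 2). Its sequence at 3R, 29736823 to 29736863, was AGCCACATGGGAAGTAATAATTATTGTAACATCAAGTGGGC. This region and those of Ugalt, Awh and RpS27 were chosen for display after their values were seen. Of the 20 strongest regions, 6 had TAATTA within 100 bp of the summit.

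Awh itself (3L, 3846206 to 3861692, plus strand) was among the genes with the most regions. Of its 14 regions, 9 lay within the gene, all in introns, and none lay at the promoter. The strongest was intronic (3L, 3850611 to 3850713, summit 4471 bp from the start), with a signal of 314, 126 in replicate 1 and 179 in replicate 2, and ranked 297 in the list. The sequence at its summit (3L, 3850657 to 3850697) was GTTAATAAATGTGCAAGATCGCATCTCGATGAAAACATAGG. The 14 signals had a median of 131 and ranged from 80.6 to 314, and 7 of the 14 regions lay in both replicates' own lists. The territory of Awh held 0.44 regions per kb, against 0.0357 per kb over the 6 chromosomes. The run of regions went on downstream to Fie (3L, 3892574 to 3894833), to whose start 13 more regions were nearest. Beyond Fie, peaks at Ccz1 (signal 472) and Ubi-p63E (275), named after their values were seen, passed the score limit but are absent from the list used. CG43245 had 16 regions, CHES-1-like, a forkhead-type gene, had 14, and hth, a homeobox gene of the TALE class, had 12 over a territory of 134 kb. CG6163 and pyd also had 12 regions each. In the list of replicate 1 alone Awh had 11 regions and Fie 4, and in that of replicate 2 alone 9 and 6. The ranked peaks that passed no threshold around Awh also had high signals, 24.1 in replicate 1 against a median of 17.1 for other region-dense windows, and 22.0 against 17.3 in replicate 2.

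**Figure D2:**
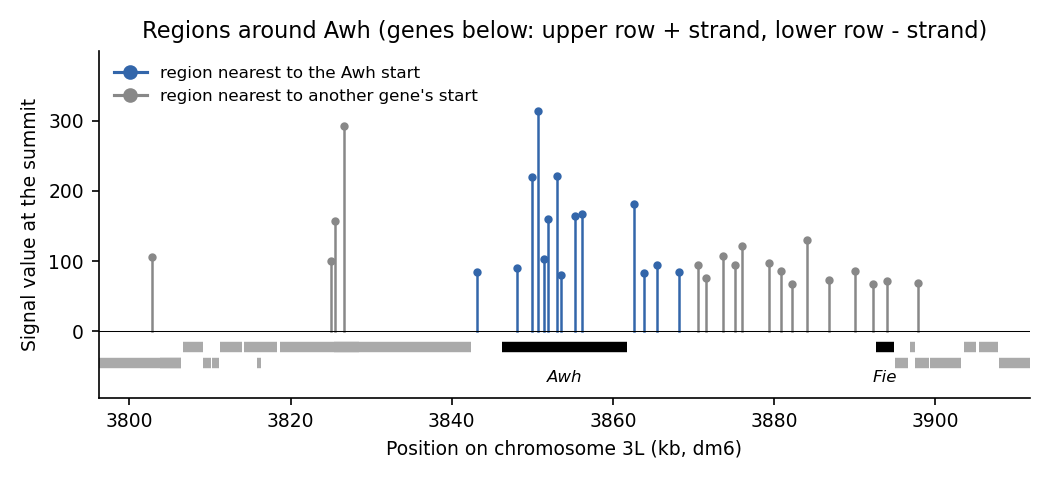
Signal value (y axis) of each bound region by its position in kb on chromosome 3L (x axis), within 50 kb of Awh, with protein-coding genes drawn as bars below the axis. The 14 regions nearest to the Awh start (blue) reach a signal of 314, and the run of regions nearest to other starts (grey) continues downstream of Awh to Fie. Peaks at Ccz1 and Ubi-p63E that are absent from the list used are not drawn.

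Bound regions were concentrated at promoters and in introns and were rare in coding sequence. Of 4781 summits, 1537 lay within 500 bp of a protein-coding start (32.1%, interval 30.8 to 33.5%), 2.80 times the mean of 11.5% for shifted summits, whose maximum was 15%. Introns held 43.5% of summits (39.2% after shifting) and intergenic sequence 1036 (21.7% against 30.3%). Only 58 summits (1.21%) lay in coding exons, where shifts placed 13.9% on average and at least 11.3%. The 3' UTRs held 38 summits (0.795% against 4.45%). In the 2-sided permutation by shifts, the adjusted p was 0.0003 for promoters, coding exons, 3' UTRs and intergenic sequence and 0.00048 for introns, at or next to the limit of the shifts, whereas 5' UTRs (32 summits) did not differ (adjusted p = 0.449). The median distance from a summit to the nearest start was 1603 bp, with quartiles of 248 and 5963 bp. Promoter regions had a median signal of 113 and other regions 102, a ratio of 1.1 (permutation test, p = 1e-05, the smallest the resamples can give). The ratio was 1.18 with the signals of replicate 1 and 1.08 with those of replicate 2.

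**Figure D3:**
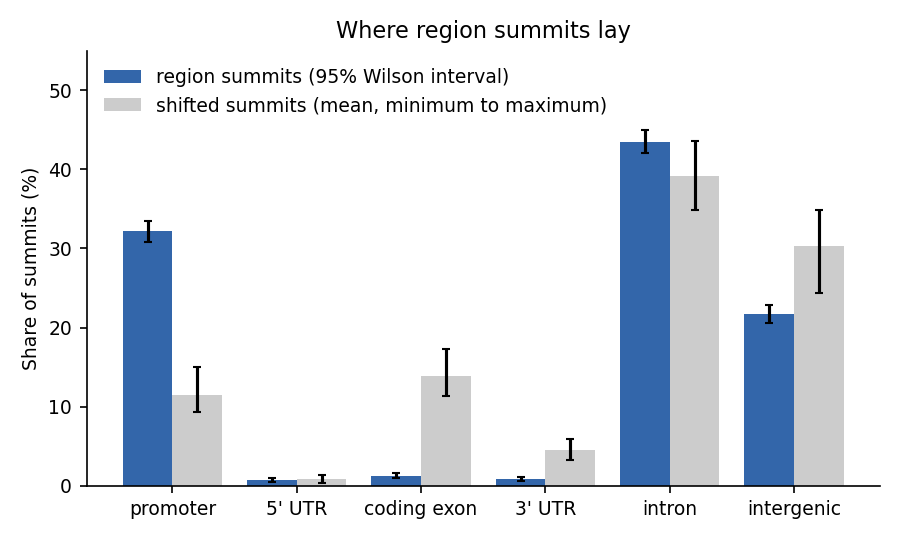
Share of region summits (y axis, %) in each class of sequence (x axis), for the 4781 regions (blue, with 95% Wilson intervals) and for 10000 circular shifts (grey, mean with minimum and maximum). Promoters hold 32.1% of summits against 11.5% after shifting, and coding exons 1.21% against 13.9%.

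TAATTA, a homeodomain core site that LIM-homeodomain proteins bind, was more frequent at summits than beside them. The presence of the site alone does not show which protein was bound there. TAATTA lay within 100 bp of 944 of 4781 summits (19.7%, interval 18.6 to 20.9%) and in 11.9% of flanking windows (exact sign test, adjusted p = 1.4e-24). In 837 regions it lay at the summit alone and in 460 in the flank alone. The regions of replicate 1 alone gave 20% against 13.2% and those of replicate 2 alone 20.1% against 12.4%. TAATTA was densest within 50 bp of summits, at 31.5 sites per 1000 regions per 20 bp, against 15.1 and 15.4 at 50 to 110 bp on either side and 13.8 beyond 150 bp. Summit windows had less GC than flanks (39.5% against 42.2%), and the composition controls were also more frequent at summits: AATATT in 24.4% against 16.2%, TTTAAA in 24.3% against 17.2%, AAATTT in 21.3% against 16.4% and TTATAA in 14.1% against 10.6%. With replicate 1 alone AATATT (28.4% against 16.4%, ratio 1.73) and TTTAAA (28.8% against 17.3%, ratio 1.67) exceeded their flanks by more than TAATTA did (ratio 1.52), whereas with replicate 2 alone TAATTA had the higher ratio (1.63 against 1.31 and 1.23). By ratio, controls also exceeded TAATTA in the stronger 50% of regions (AATATT 1.71 against 1.65) and, in a set chosen after seeing the data, at promoter regions alone (TTTAAA 1.88 and AAATTT 1.87 against 1.78). In the main setting TAATTA had the higher ratio (1.66 against 1.51 for AATATT), but in percentage points AATATT rose slightly more. TAATTA was not tested against the controls. The extended palindrome CTAATTAG lay in 0.858% of summit and 0.46% of flank windows (exact sign test, adjusted p = 0.0429). That call was lost with replicate 1 alone (exact sign test, adjusted p = 0.143), in the stronger 50% of regions (0.151), within 200 bp of summits (0.193) and with flanks 2000 bp away (0.298). It was kept with replicate 2 alone (1.1% against 0.14%, exact sign test, adjusted p = 2.15e-07), the optimal list (0.000502) and unmerged peaks (0.00844). The direction was the same with replicate 1 alone (0.622% against 0.276%), and a difference between the replicates was not tested. With random windows matched for GC, TAATTA was still more frequent at summits (19.7% against 14.3%, exact sign test, adjusted p = 8.68e-12), and so were AATATT (24.4% against 19.2%, adjusted p = 5.21e-10), TTTAAA (24.3% against 21.4%, adjusted p = 0.000703) and TTATAA (14.1% against 11.8%, adjusted p = 0.0011). AAATTT did not pass the exact sign test there (21.3% against 22.8%, adjusted p = 0.0991). In a combination chosen after seeing the data, windows of 50 bp on either side with GC-matched controls, TAATTA had 13.7% against 8.48% (exact sign test, adjusted p = 2.95e-15) TTTAAA, TTATAA and AAATTT did not pass (adjusted p = 0.503, 0.3 and 0.487), and AATATT still did (14.5% against 12.1%, adjusted p = 0.000895).

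**Figure D4:**
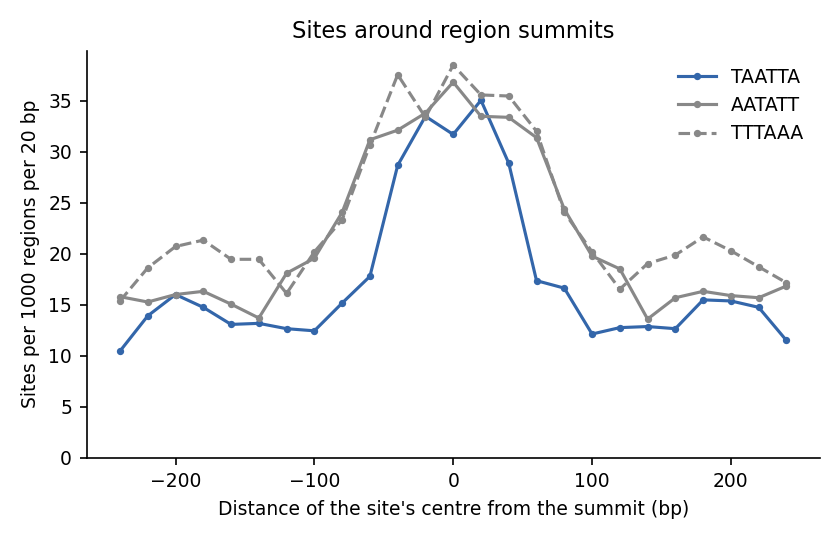
Number of sites per 1000 regions in bins of 20 bp (y axis) by the distance of the site from the summit in bp (x axis), for TAATTA (blue) and for the palindromes AATATT and TTTAAA of the same base composition (grey). All 3 rise at the summit, TAATTA from 13.8 beyond 150 bp to 31.5 within 50 bp.

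Of the sites of other factors, those of DREF, GAGA factor and forkhead proteins were more frequent at summits in the main setting and TAATCC was less frequent. The site TATCGATA of DREF, a regulator of promoters of widely expressed genes, lay at 1.72% of summits against 0.502% of flanks (exact sign test, adjusted p = 2.96e-08), and at promoter regions at 4.49% against 0.455%, a split chosen after seeing the data. Outside promoters it did not differ (0.401% against 0.555%, exact sign test, adjusted p = 0.636). GAGAG, the site of GAGA factor, had 26.4% against 22.2% (exact sign test, adjusted p = 3.03e-06), a call that was not made with replicate 1 alone (adjusted p = 0.378) or within 50 bp of summits (0.379). The forkhead core TGTTT had 65.9% against 59.0% (exact sign test, adjusted p = 1.71e-11). The K50-homeodomain site TAATCC was less frequent at summits (5.19% against 7.09%, exact sign test, adjusted p = 0.000229), again not with replicate 1 alone (adjusted p = 0.922), in the stronger 50% of regions (0.849) or, in settings chosen after seeing the data, with GC-matched windows of 50 bp (0.175) and in promoter regions alone (0.226). Sites of Zelda (CAGGTAG, 1.25% against 1.28%), Grainyhead (ACCGGT, 1.36% against 1.38%), GATA factors (GATAAG, 10.4% against 9.56%), Su(H) (GTGGGAA, 2.18% against 2.57%), M1BP (GGTCACA, 2.07% against 1.86%), Caudal (TTTATGG, 6.17% against 6.0%), TALE factors (TGACAG, 6.8% against 6.46%) and both E-boxes (CACCTG, 6.25% against 7.32%, and CAGCTG, 8.76% against 9.43%) did not pass the test in the main setting. Some did in other settings of the exact test. CACCTG was less frequent at summits with the optimal list (exact sign test, adjusted p = 0.013), replicate 1 alone (0.00227), the stronger 50% of regions (0.00279), unmerged peaks (0.00427), windows of 50 bp (0.000585) or 200 bp (0.04) and flanks 2000 bp away (0.0109), but not with replicate 2 alone (0.245), GC-matched windows (0.131) or regions outside promoters (0.583). CAGCTG passed in opposite directions, higher with GC-matched windows (exact sign test, adjusted p = 0.00091) and within 200 bp (0.000479) and lower within 50 bp of summits against flanks (0.0374), in the stronger 50% (0.0378) and outside promoters (0.0348). GATAAG was higher with the optimal list (exact sign test, adjusted p = 0.0196) and GC-matched windows (0.00168), GGTCACA was higher within 200 bp (0.00245), and GTGGGAA was lower with unmerged peaks (0.0371) and within 50 bp (0.0374). In settings chosen after seeing the data, the exact sign test called CAGCTG and GATAAG higher with GC-matched windows of 50 bp (adjusted p = 0.0378 and 0.0396), and at promoter regions alone GGTCACA higher (0.0167) and CACCTG and CAGGTAG lower (0.000363 and 0.0409).

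Of all hexamers, tested by the same exact sign test, 304 were more frequent at summits and 488 less frequent. In the main setting, the lowest p belonged to ACAGTG, which lay in 16.1% of summit windows and 7.8% of flanks (exact sign test, adjusted p = 7.62e-33). ACACTG (14.9% against 7.53%) and AGTGTA (13.9% against 7.2%) were close to it, and AT-rich hexamers such as AAATAT (41.8% against 29.9%) and AATTAA (37.8% against 26.4%) made up most of the rest of the 12 with the lowest p among hexamers more frequent at summits, in which TAATTA ranked 9. Read 5' to 3' on its own strand, ACAGTG was densest 50 to 110 bp before the summit, at 38.3 sites per 1000 regions per 20 bp. Its density was 13.3 within 50 bp of the summit and 12.5 as far behind it. It occurred 549 times before and 179 times behind the summit at these distances (exact binomial test, p = 1.59e-44). That test compares the 2 sides and counts occurrences as independent. Among hexamers less frequent at summits, GCAGGA had the lowest p (3.62% against 9.35%, exact sign test, adjusted p = 3.34e-28). With GC-matched windows of 50 bp on either side, chosen after seeing the data, TAATTA had the lowest p of the hexamers above the controls, followed by AATTAA (25.3% against 19%) and ATTAGC (8.19% against 4.88%), out of 116 hexamers called more frequent at summits. In settings fixed in advance TAATTA ranked 2 with windows of 50 bp alone, and was not among the 12 lowest with GC-matched windows of full width, with replicate 1 alone or in the stronger 50% of regions. ACAGTG ranked 1 with GC-matched windows of full width, 2 with replicate 2 alone, 3 with replicate 1 alone and 9 in the stronger 50%. It was not among the 12 lowest with windows of 50 bp alone.

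Genes of several kinds had regions more often than their territories would give. The cytoplasmic ribosomal protein genes stood out, with 55 of 92 bound against 13.6 expected (4.04 times, exact test, adjusted p = 2.36e-24), and 52 of their 58 regions were at promoters. RpS27 had the strongest of these (3R, 25247406 to 25247602, summit 12 bp from the start), with a signal of 402, 188 in replicate 1 and 223 in replicate 2. The 41 bp around its summit (3R, 25247482 to 25247522) read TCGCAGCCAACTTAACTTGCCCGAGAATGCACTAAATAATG. RpL7 (378), RpL41 (293) and RpS4 (246) followed. The list of replicate 1 alone gave 36 bound members and that of replicate 2 alone 48. Proteasome subunit genes, another set used by every cell, had 3 of 32 bound against 3.83 expected (exact test, adjusted p = 1), at Rpn3 (signal 187), Rpn9 (78.1) and Rpn6 (73.8).

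Components and targets of the Notch, EGFR, Wnt, Hedgehog and Dpp pathways were bound in 25 of 39 cases against 12.9 expected (1.94 times, exact test, adjusted p = 0.000259). In contrast to the ribosomal protein genes, 12 of their 83 regions were at promoters. The strongest was in an intron of aos, which encodes a secreted inhibitor of the EGF receptor (3L, 16480470 to 16480656, signal 415, 231 in replicate 1 and 180 in replicate 2). Others lay at the promoter of nkd, a Wnt pathway antagonist (300), and in introns of pnt (271) and aop (259), which encode ETS factors downstream of the EGF receptor. With summits required to lie within 1000 bp of a start, this list had 14 bound genes and its call was lost (exact test, adjusted p = 0.0713).

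Imaginal disc and histoblast patterning genes, the list closest to the known role of Awh, had 25 of 35 bound against 15.4 expected (1.63 times, exact test, adjusted p = 0.00573). Only 6 of their 68 regions were at promoters. The strongest lay in an intron of hth (3R, 10590200 to 10590360, signal 342, 135 and 195 in replicates 1 and 2), in an intron of bab2 (205), at the promoter of Dll (199), a regulator of limb formation, and near eyg (193). The signals at bab2 were 49.3 and 145 in the replicates, a larger gap than at the other 3. In the exact test the call was lost with replicate 1 alone (19 bound, adjusted p = 0.0554), with the stronger 50% of regions (15 bound, adjusted p = 0.245) and with summits within 1000 bp of a start (7 bound, adjusted p = 1). Salivary gland genes had 10 of 16 bound against 5.23 expected, which did not pass after adjustment (exact test, p = 0.0198, adjusted p = 0.0593). The list did pass the exact test with replicate 1 alone (9 bound, adjusted p = 0.0371), with summits in the gene body or 2000 bp upstream (0.0397), without territory bins (0.000732) and in regions without facing ACAGTG or ACACTG, a set chosen after seeing the data (0.0165), but not with replicate 2 alone (0.0614), in the stronger 50% of regions (0.186) or within 1000 bp of a start (0.434). Their strongest regions were at sano (289), at the promoter of fkh (241), which encodes a forkhead regulator of the gland, at rib (211) and at eyg (193).

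Chemosensory receptor and odorant-binding protein genes were bound less often, 20 of 226 against 46.2 expected (0.433 times, exact test, adjusted p = 8.47e-06). The strongest of their regions were assigned to Obp51a (280), Obp83cd (254), Obp99b (223) and Or65c (193). The other lists did not pass the exact test. Hox and homeotic genes had 10 of 17 bound against 6.35 expected (exact test, adjusted p = 0.215), with hth, bcd (164), Antp (124) and Dfd (116) the strongest. Endoderm, trachea and blood genes had 11 of 20 against 6.9 (exact test, adjusted p = 0.209), led by ush (340), fkh, knrl (190) and crq (143). Axon guidance genes had 16 of 29 against 12.1 (exact test, adjusted p = 0.333), led by PlexA (301), Sema1a (274), caps (214) and Fas3 (206). Segmentation genes had 14 of 28 against 11.0 (exact test, adjusted p = 0.451), led by slp2 (380), nkd, ptc (245) and ems (207). Mesoderm and muscle genes had 13 of 28 against 10.1 (exact test, adjusted p = 0.451), led by the promoter of tin (392), lbe (365), Mef2 (257) and kirre (253). LIM-homeodomain factors and their cofactors had 4 of 10 against 3.78 (exact test, adjusted p = 1), namely Awh, Lim1 (126), Bx (113) and tup (106). The cofactor gene Ssdp counted as unbound, although 2 ranked peaks nearest to it (119 and 106) passed the score limit and are absent from the list used. Neural progenitor and neuronal identity factors had 14 of 40 against 14.3 (exact test, adjusted p = 1), led by Dr (428), zfh2 (378), vvl (308) and D (241). Epidermis and cuticle genes had 5 of 15 against 5.34 (exact test, adjusted p = 1), led by Fas3, sn (179), crb (148) and ovo (129). The list named synapse and channel genes had 5 of 23 against 8.32 (exact test, adjusted p = 0.333). Its strongest regions were at the promoter of elav (361), fne (155), comt (138) and Syx1A (127), and elav and fne are neuronal genes of another kind. A p above the threshold does not show that a list was bound at the background rate, since lists of this size can miss a 3-fold rise in odds.

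**Figure D5:**
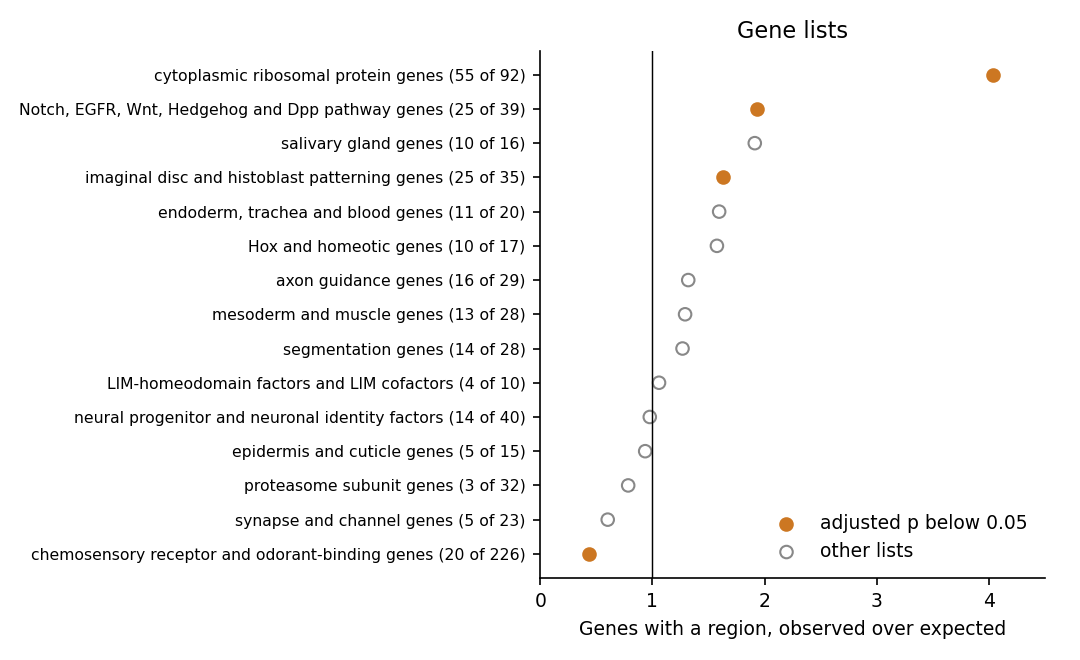
Genes with a region in each of the 15 lists, observed over expected from territory length (x axis), with bound and total members in brackets. Filled points have an adjusted p below 0.05: 3 lists lie above 1, the ribosomal protein genes at 4.04, and the chemosensory genes lie below it at 0.433.

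Apart from the sparse chromosome 4, regions were spread over the chromosome arms with modest differences. Chromosome 3L, which carries Awh, had 39.8 regions per Mb, more than its share of the length (exact binomial test, adjusted p = 0.000193), as did 2L with 38.3 (adjusted p = 0.0339). Chromosomes 2R with 35.2 and 3R with 35.1 did not pass the exact test (adjusted p = 0.618 for each). The X had 31.5 per Mb, or 741 regions (15.5% of all against 17.6% of the length, exact binomial test, p = 0.000134, adjusted over the 6 chromosomes p = 0.000267). The small chromosome 4 had 6 regions (4.45 per Mb, exact binomial test, adjusted p = 2.74e-13), among them the region of zfh2 (4, 497846 to 498009, signal 378) and the PlexA promoter (4, 1027220 to 1027377, signal 301). The lower density on X was not called with replicate 1 alone (exact binomial test, p = 0.272) or among the stronger 50% of regions (p = 0.361). These tests treat regions as independent, and neighbouring regions are not. They also compare X with its length alone, although the dose of X differs between the sexes.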

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

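The tests in this part were chosen after the results were seen, except that of facing pairs in coding exons, whose limits were set before its result was seen.

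Candidate peaks outside the main measurement stood out because 123 of the 5149 peaks of the ranked list that pass the score limit are not in the conservative list as used here. They included a peak that ranked 3 among all passing peaks, 1410 bp upstream of the cbt start (2L, 480955 to 481233, signal 1343), and a peak near Lk6 (3R, 11760930 to 11761164, signal 1059), both named after their values were seen. Of the genes in the fixed lists, Ssdp (signals 119 and 106) and RpL13A (151) had such peaks and no region in the list used, so they count as unbound here. The 123 had a median signal of 95.5 against 102 for listed peaks, and they made up 5.25% of the passing peaks on 3R and 0.256% of those on X.

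The crowding of regions around Awh, the gene whose product was tagged, could have a technical source, since the labels describe an insertion targeting Awh and extra copies of a locus raise the signal along its length. Within 20 kb of Awh, ranked peaks that passed no threshold had a median signal 1.40 times that of 50 other region-dense windows in replicate 1 and 1.28 times in replicate 2, and 0 of the 50 windows were as high in either replicate, although these held 10 to 20 regions against 22 around Awh. The limit set for extra copies was 1.3 in both replicates, so this test leaves them open. Binding of Awh to its own locus is also open, since 4 of the 22 summits there have TAATTA (18.2%, interval 7.31 to 38.5%), a range that includes the flank share of 11.9%. A control library from the same flies, not analysed here, would separate the explanations.

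ACAGTG and ACACTG lay beside summits and faced them from either side. Both sides carried a facing site in 245 regions against 110 expected by independence (odds ratio 3.80, Fisher's exact test, p = 1.46e-43), and sites facing away showed no such excess (26 against 20, Fisher's exact test, p = 0.151). The facing sequences alone, as in preferred amplification of some fragments, were tested with facing pairs 100 to 240 bp apart in the genome. In coding exons 1 of 500 pairs lay in a region, against 254 of 2799 in introns and intergenic sequence. The ratio of rates was 0.022 (upper limit 0.124), which met the limit set against this explanation. However, regions of all kinds were rare in coding exons (1.21% of summits against 13.9% after shifting). A low ratio was therefore likely beforehand and weighs little against the facing sequences alone. A paired element of noncoding DNA may account for the pattern, as may a bias that also needs open chromatin or the AT-rich sequence between the sites, and neither was tested.

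Ribosomal protein promoters were bound far more often than their territories would give, and 2 simple explanations were tested. The tables argue against binding through TAATTA at most of these regions, since 3 of 52 have the site within 100 bp (5.77%, interval 1.98 to 15.6%). The share was 18.1% at other promoter regions (Fisher's exact test, p = 0.0244), most of which therefore lack the site too. All ribosomal protein starts, bound or not, had 4.52%. The low share is thus that of the gene class and is not particular to its bound promoters. Signal at every widely expressed promoter is argued against as well. Of 173 genes for proteasome subunits, ATP synthase, translation factors, the T-complex and mitochondrial ribosomal proteins, 21 were bound (12.1%, interval 8.08 to 17.8%). The share was 59.8% for ribosomal protein genes (interval 49.6 to 69.2%). Expression itself was not measured here and the sets were not matched for it, so signal that rises with expression was not tested. Recruitment by another protein, or background that is particular to these promoters, may be the source and cannot be resolved without a control library.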

How the results depend on the processing

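Of the results that answer a question of the design, every alternative kept the direction and the side of the threshold for replicate overlap, promoter share, TAATTA share and signal by position. The replicate overlap ranged from 64.4% to 79.5%, the promoter enrichment from 2.07 (within 1000 bp) to 4 (within 250 bp), the TAATTA difference from 5.25 to 8.16 percentage points and the signal ratio from 1.06 to 1.16. Leaving out a replicate gave 2895 to 3560 regions, X shares of 0.843 to 0.955 of the length share (weaker without replicate 2, as given in the report) and 236 to 333 hexamers more frequent at summits. The stronger 50% of regions, 2390 by construction, gave an X share of 0.959, past no threshold, and a rho of 0.594, and the optimal list a rho of 0.577. Gene lists past the threshold numbered 4, but 2 with summits within 1000 bp of a start, 11 without territory bins, 3 in the stronger 50% of regions, 5 with summits in the gene body or 2000 bp upstream and 5 in regions without facing sites. Enriched hexamers fell from 304 to 116 with 50 bp GC-matched windows and to 192 in the 3575 regions without facing ACAGTG or ACACTG. These 2 settings were chosen after seeing the data, and the cause of these shifts was not tested. Reversals of results that had passed the threshold were 4. The difference between summit and GC-matched random windows was -1.46 percentage points for AAATTT, and -0.586 with 50 bp windows as well. The summit minus flank difference was -0.154 for TATCGATA outside promoters, and the imaginal disc list stood at 1.0 times expectation within 1000 bp of starts. None of these 4 passed the threshold. Among single sites, lists and genes under all alternatives, 596 values kept their side, 186 moved, 28 gained and 17 lost a call. With 2 replicates of a single group, no paired fit or block for replicates was needed. Read totals are unknown, so what depth limits could not be assessed.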

Other observations

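All tests of this part were chosen after the main results were seen.

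TAATTA was more frequent at summits than in flanks in every class of signal strength. In the weakest 20% of regions (956 regions, signals up to 78.0) it lay near 15.7% of summits against 12.3% of flanks (exact sign test, unadjusted p = 0.0443), and in the strongest 20% (957 regions, signals from 173) near 22.2% against 11.7% (p = 1.7e-09). The difference between summit and flank was 9.0, 8.26 and 8.37 percentage points in the groups between them. The promoter share went from 28.1% in the weakest 20% to 41.1% in the strongest. The change of TAATTA across these groups was not itself tested.

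Of the 15 gene lists, chemosensory genes alone passed a test of the share of their regions with TAATTA. Although chemosensory genes were bound less often than expected, 13 of their 29 regions had TAATTA within 100 bp of the summit (44.8%, interval 28.4 to 62.5%, Fisher's exact test against all other regions, adjusted p = 0.0277). The share was 25% for the 68 regions of imaginal disc and histoblast genes (Fisher's exact test, adjusted p = 0.846) and 8.62% for the 58 regions of ribosomal protein genes (adjusted p = 0.228). Such shares count regions assigned to the nearest start, which need not act on that gene. They were not compared with flanks, GC-matched windows or control palindromes, so local base composition was not controlled for.

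Lists of genes with general cellular functions, added beside the cytoplasmic ribosomal protein genes, showed no such excess. None of 10 ATP synthase genes had a region (upper Wilson limit 27.8%), while 9 of 50 translation initiation and elongation factor genes did, among them eEF1alpha1 and eIF3c, against 9.34 expected. Mitochondrial ribosomal protein genes had 8 of 73 bound against 8.41 expected, although mRpS10 and mRpL41 were among the 20 strongest regions. The exact test gave an adjusted p of 1 for each of these lists, which are small enough that a difference can be missed.

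Regions with ACAGTG or ACACTG facing the summit from both sides were stronger, with a median signal of 145 against 102 for regions with neither. In replicate 1 alone the medians were 92.5 and 68.6, and in replicate 2 alone 80.5 and 62.8. TAATTA within 50 bp lay in 10.2% of the former and 14.2% of the latter, a difference that did not pass Fisher's exact test (p = 0.0861). The shares were 9.95% (interval 6.53 to 14.9%) and 13.5% (12.1 to 15.1%) in replicate 1 alone, and 7.07% (4.18 to 11.7%) and 13.6% (12.3 to 14.9%) in replicate 2 alone, where the intervals did not overlap.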
